A study of Caenorhabditis elegans with 2 samples.

How the data were processed

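The samples were 2 biological replicates of 1 group, whole L2 larvae with eGFP-tagged NHR-77, assayed by ChIP-seq. Per the labels, the antibody is listed under the name of the target protein and the assay is described as against the eGFP fusion. The deposited files were lists of regions in narrowPeak format: a relaxed list of each replicate, a relaxed list of both replicates pooled, and the authors' list of peaks past their threshold on the irreproducible discovery rate, each on builds ce11 and ce10. According to the authors' text files, the relaxed lists were derived from the alignments and a control file, and the thresholded list from the pooled and replicate lists. The peaks were thus called by the authors on pooled replicates. The thresholded list was exactly the 415 highest pooled regions, so single peaks were not each required to stand in both replicates: 409 overlapped a relaxed region of replicate 1 and 415 of replicate 2. The aligner, the peak caller and their versions are not given in the sources used here. No control sample, read or coverage track was used here.

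The values read from each deposited list were the signal value, a score of the authors' peak caller whose scale is not stated, and the q-value column, given by the authors as a −log10 q-value. Score sizes depend on depth and were not compared between lists: ranks were used across lists, with log2 scores only for Pearson's r. The −log10 q-value ran from 2.20 to 2.88 over the thresholded peaks and was used only to check the files. The number of reads per library is unknown from the files, so no interval here covers depth. Results are for ce11, with positions counted from 1, and ce10 was an alternative. The 415 ce11 peaks included 5 pairs of adjacent overlapping entries, which were kept apart. Genes came from the Ensembl annotation, release 115, and sequence from the reference genome WBcel235, the same assembly as ce11.

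N denotes the number of thresholded peaks. Replicates were compared by the share of the N highest regions with summits within 100 bp, against 10000 random draws, and by correlations over peaks with permutation tests of 100000 resamples, adjusted by the Benjamini-Hochberg method over the 3 sets of peaks. Gene starts were annotated 5′ ends of protein-coding genes, and a summit within 500 bp counted as near. Annotation classes also used protein-coding genes only, so intergenic means outside those genes and may include non-coding genes. The background was every pooled relaxed region that did not overlap a peak. Gene lists were tested over genes nearest, within 2000 bp, to at least 1 pooled relaxed region. Short RNA genes counted within 500 bp. Sequence patterns were searched on both strands of 200 bp windows, against 5 background windows per peak drawn with seed 1 from the same bin of 2 percentage points of GC content, and 11 of the controls sought could not be found. Fisher's exact tests were two-sided, with Benjamini-Hochberg adjustment within each family (6 chromosomes, 5 features, 20 gene lists, 5 RNA classes, 9 patterns, 2080 hexamers) and a threshold of 0.05. The signal at nhr-77 and unc-119 was summed over the gene and 15 kb on each side and ranked among windows of the same length on all protein-coding genes.

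Named genes followed a rule: the genes assigned to the 25 peaks with the highest signal; nhr-77 and unc-119; up to 4 members with the highest signal of each list that passed; the same for nuclear receptors, molting and timing genes and tissue markers whether or not they passed; and the 5 hexamers with the lowest p. The comparisons, the gene lists, this rule and the alternatives were chosen before the data were examined, except where the text says otherwise. The split of gene starts by chromosome, the annotation classes, the comparison of the 25 highest peaks with the rest, the pooled tissue markers, the count of CG in hexamers and the test of the 12-base motif were chosen after.

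The alternatives were: ce10 lists, merged entries, and peaks found in both replicates; other summit distances (50 and 200 bp, or any overlap) and other N; matching by nearest summit; the upper 208 peaks; the N highest nuclear regions of each replicate alone, that is, without the other replicate; the N highest pooled regions; gene start distances of 250 and 1000 bp; region midpoints; the 10000 highest background regions; chromosome length as background; assignment within 500 or 5000 bp or to all genes within 1000 bp; all annotated genes as background; random draws in place of Fisher's test; short RNA distances of 200 and 1000 bp; windows of 100 and 400 bp; controls also matched on gene start; no GC matching; and other windows and region counts at the transgene loci. Alternatives added after the data were seen were nuclear regions only, the 25 highest peaks only, leaving out peaks near short RNA genes, and leaving out X peaks.

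The tests were tried on simulated data drawn from the relaxed list. With no change placed, 0.2 of 100 gene list tests, 4% of gene start tests and 1.11 of 100 pattern tests were called, and no hexamer was called. With 20 regions of 1 list added, with 25% of regions drawn near gene starts, or with AGGTCA placed in 10% of windows, the placed change was called in 100% of runs. The added list was cuticle collagens, with 100 genes in the background, so its result does not carry over to small lists such as heat shock proteins, with 14. Smaller changes were not tried, so the runs do not show what size of effect could be missed. The draws without a change were random background regions, so they do not cover the GC content and closeness to gene starts of the peaks. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.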

Results

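Chromatin immunoprecipitation sequencing (ChIP-seq) was used to map where NHR-77, a nuclear hormone receptor of *Caenorhabditis elegans*, sits on the genome of whole L2 larvae. Per the labels the worms, of both sexes, carried a transgene for eGFP-tagged NHR-77 in an unc-119 mutant background (strain OP353). There was 1 group with 2 biological replicates, so the comparisons that the design allows are between the replicates and between kinds of region within the lists. The authors' list of peaks past their reproducibility threshold held 415 peaks on genome build ce11, which covered 133 kb. Their signal values, the peak caller's own score, ranged from 27.1 to 244.8 with a median of 36.98. These peaks were compared with the relaxed list of 30000 pooled regions from which they came, of which 29553 did not overlap a peak and served as background. The relaxed list of replicate 1 held 23256 regions and that of replicate 2 held 30000. The number of reads behind each list is unknown from the files. All p-values below concern regions or genes, which are not independent replicates of animals, and intervals are 95% Clopper-Pearson intervals that cover counting error only.

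The question of the comparison between the replicates was how far the same regions stood highest in both. Of the 415 highest regions of replicate 1, 171 (41.2%, interval 36.4 to 46.1) had a summit within 100 bp of a summit among the 415 highest of replicate 2. Random draws from the same lists shared 0.188% on average and 1.45% at most (one-sided permutation test, p = 0.0001, the smallest that 10000 draws can give). The draws were not matched on GC content or closeness to gene starts. Regions that share only such features could also exceed them, so the test does not show that the shared regions are bound by NHR-77. The peaks at the top of the pooled list stood high in both replicates. The highest peak, on X, ranked 13 in replicate 1 and 1 in replicate 2, the peak by rpl-3 ranked 24 and 4, and the peak by cdc-48.1 ranked 17 and 6. Ranks in replicate 1 count mitochondrial regions, which were 15 of its 25 highest and are absent from the list of replicate 2, so nuclear peaks rank lower there. Lower in the list the replicates parted: 177 of the 415 peaks (42.7%) lay within 100 bp of a summit among the 415 highest regions of both replicates, 158 (38.1%) of replicate 2 only, 41 (9.88%) of replicate 1 only and 39 (9.40%) of neither. The thresholded peaks were exactly the 415 pooled regions with the highest signal.

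Across the 409 peaks with a region in both replicates, the signal values of the replicates were correlated, with Spearman's rho = 0.394 and Pearson's r = 0.542 on the log2 scale. The 88 X peaks had rho = 0.662 and r = 0.768, and the 321 autosomal peaks had rho = 0.300 and r = 0.396. Each of these correlations is across regions, not samples, and each had a permutation p = 1e-05 before and after adjustment, the smallest that 100000 permutations can give. X held 16 of the 25 highest peaks, so X and autosomal peaks differ in their range of signal. The difference between their correlations was not tested and cannot be read as a difference in reproducibility.

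**Figure D1:**
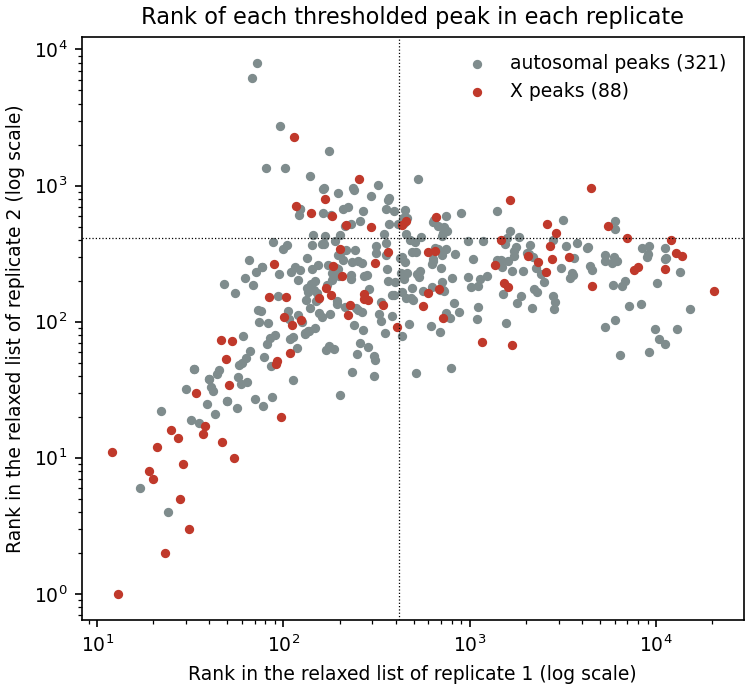
Rank of each thresholded peak in the relaxed list of replicate 1 (x axis, log scale) and of replicate 2 (y axis, log scale), for the 409 peaks with a region in both, with X peaks in red and autosomal peaks in grey and dotted lines at rank 415. Peaks with the lowest rank numbers in one replicate also have low rank numbers in the other, while many peaks beyond rank 415 of replicate 1 lie within the 415 highest of replicate 2.

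The strongest peaks lay on the X chromosome, most of them away from annotated gene starts. Of the 25 peaks with the highest signal, 16 (64%) were on X, against 73 of the other 390 (18.7%; Fisher's exact test, two-sided, p = 2.36e-06). The highest, with signal 244.8, spanned X 11094022 to 11094330 in intergenic sequence 3993 bp from the start of W02H3.3. The sequence of 61 bp around its summit (11094163 to 11094223) reads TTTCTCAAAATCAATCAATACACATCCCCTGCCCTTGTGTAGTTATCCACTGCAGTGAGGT. The next, with signal 207, spanned X 9465754 to 9465992, 2520 bp from the start of ZK899.6. Other X peaks of this set lay in an intron of Y41G9A.17 (X 2996964 to 2997204, signal 182), in an intron of mom-1, which encodes a protein needed for Wnt secretion (X 6296485 to 6296666, signal 173), and in a coding exon of the polyketide synthase gene pks-1 (X 5429488 to 5429597, signal 137). A further X peak (8036310 to 8036559, signal 150) was 4828 bp from the start of xol-1, the switch gene of sex determination. Of the 16 X peaks, 13 were intergenic (outside protein-coding genes), 2 intronic and 1 in a coding exon.

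7 of these X peaks lay within 2000 bp of the start of a protein-coding gene. These genes were F19H6.5 (WBGene00008960, peak X 12363068 to 12363291, signal 190), nspc-17 (WBGene00008359, X 14525749 to 14526035, 189), F20B6.9 (WBGene00017632, X 4209171 to 4209371, 180), F55G7.5 (WBGene00195215, X 11937457 to 11937642, 178), the F-box gene fbxb-58 (WBGene00019186, X 1627050 to 1627238, 157), the insulin-like peptide gene ins-39 (WBGene00017668, X 1344980 to 1345147, 140) and T27A8.7 (WBGene00206527, X 16056478 to 16056637, 110). Their distances to the summit ran from 612 bp for ins-39 to 1781 bp for F20B6.9. The genes by the other 9 X peaks, xol-1 among them, lie beyond the distance set for naming genes and were named after their values were seen, to place the peaks.

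The 9 autosomal peaks among the 25 were all intergenic and lay 84 to 458 bp from a gene start. Those with the highest signal were by rpl-3 (WBGene00004414, peak III 3867453 to 3867693, signal 186, 285 bp from the start), which encodes a ribosomal protein of the large subunit, and by cdc-48.1 (WBGene00007352, II 10563468 to 10563674, signal 184, 159 bp), which encodes an ATPase that unfolds ubiquitin-marked proteins. The sequence of 61 bp around the rpl-3 summit (III 3867539 to 3867599) reads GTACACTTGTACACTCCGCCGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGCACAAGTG, and that around the cdc-48.1 summit (II 10563536 to 10563596) reads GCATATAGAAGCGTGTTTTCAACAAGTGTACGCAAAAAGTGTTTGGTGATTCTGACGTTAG. The others were by Y17G9B.5 (WBGene00021202, IV 4749998 to 4750160, signal 134), R09E12.9 (WBGene00044514, V 777418 to 777596, 127), rpl-15 (WBGene00004427, IV 654846 to 655001, 117), the mRNA cap methyltransferase gene cmtr-1 (WBGene00013160, II 15025931 to 15026025, 115), the kinetochore gene ska-3 (WBGene00018830, III 5679067 to 5679200, 109), rpl-35 (WBGene00004449, III 7854621 to 7854752, 107) and the histone methyltransferase gene set-16 (WBGene00011729, III 13643585 to 13643914, 103).

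**Figure D2:**
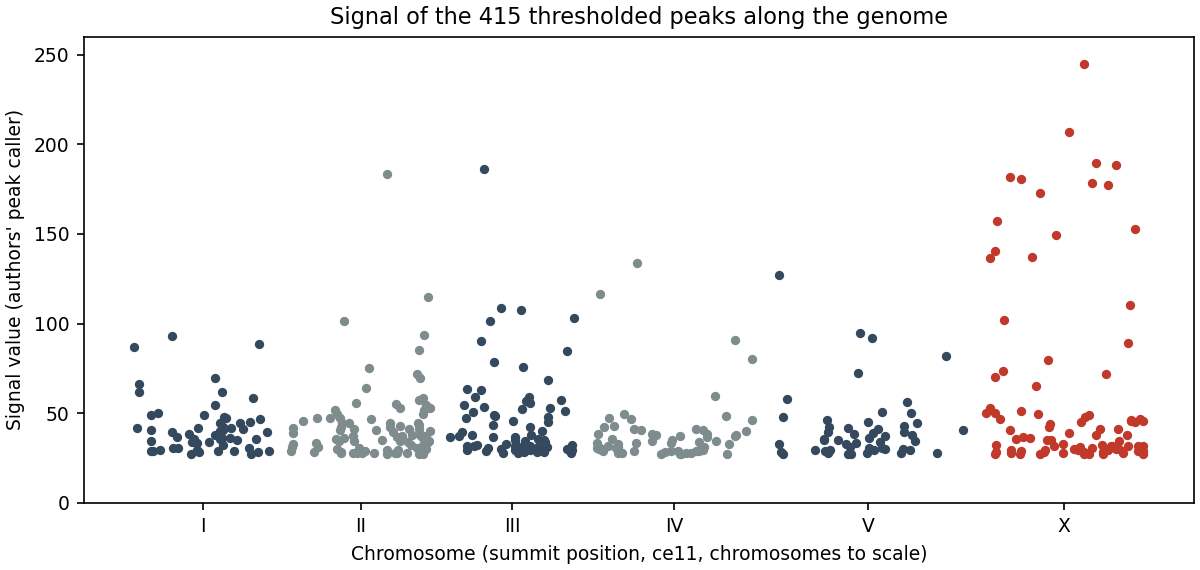
Signal value of the authors' peak caller (y axis) of each of the 415 thresholded peaks at its summit position (x axis, ce11, chromosomes to scale), with X in red and the autosomes in alternating blue and grey. 16 of the 25 highest peaks are on X, while rpl-3 on III and cdc-48.1 on II have the highest autosomal values.

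Over all 415 peaks the chromosomes differed less. Chromosome II held 88 peaks (21.2%, against 15.8% of background regions; odds ratio 1.43, exact adjusted p = 0.0108) and chromosome V held 51 (12.3% against 19.04%; odds ratio 0.596, adjusted p = 0.00187). X held 89 (21.4%, interval 17.6 to 25.7, against 17.7%; odds ratio 1.27), which did not pass the test (exact adjusted p = 0.105). Chromosomes I (57 peaks, exact adjusted p = 0.374), III (71, adjusted p = 0.288) and IV (59, adjusted p = 0.221) did not pass either. These are two-sided Fisher's exact tests adjusted over 6 chromosomes. The share on X passed with the 415 highest nuclear regions of replicate 1 alone (22.4%, exact adjusted p = 0.0428), and among the 25 highest peaks chromosome II held 8% (adjusted p = 0.495) and V held 4% (adjusted p = 0.140). Chromosome IV passed as lower with replicate 1 alone (13.01%, exact adjusted p = 0.0428) and with replicate 2 alone (12.5%, adjusted p = 0.0294), and III as higher with replicate 1 alone (19.04%, adjusted p = 0.0428).

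Peaks gathered in intergenic sequence close to the starts of protein-coding genes. A start lay within 500 bp of the summit of 241 of the 415 peaks (58.1%, interval 53.2 to 62.9), against 6522 of 29553 background regions (22.1%, interval 21.6 to 22.5; Fisher's exact test, two-sided, odds ratio 4.89, p = 1.64e-55). The median distance to the nearest start was 330 bp for peaks and 1520 bp for background. Autosomal peaks and X peaks differed: 213 of 326 autosomal peaks (65.3%) and 28 of 89 X peaks (31.5%) were near a start (odds ratio 0.244 for X, exact p = 1.39e-08). Among the 25 highest, none of the 16 X peaks (upper limit of the interval 20.6%) and all 9 autosomal peaks lay within 500 bp of a start (Fisher's exact test, p = 4.89e-07).

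By annotation, 329 peaks (79.3%) were intergenic, that is, outside protein-coding genes, against 38.9% of background regions (odds ratio 6.02, exact adjusted p = 1.21e-61). Non-coding genes were not among the classes, so some of these summits may lie in such genes. Introns held 63 peaks (15.2% against 35.96%, exact adjusted p = 1.49e-20), coding exons 3 (0.723% against 18.6%, adjusted p = 6.50e-32) and 3′ UTRs 7 (1.69% against 4.68%, adjusted p = 0.00254), all lower shares than background. The 13 peaks in 5′ UTRs (3.13% against 1.86%) did not differ by the test (exact adjusted p = 0.0661).

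Genes for ribosomal proteins and heat shock proteins stood out among the genes by peaks. With each peak assigned to the nearest start within 2000 bp, 328 peaks fell to 321 genes, out of 11572 genes that any relaxed region could reach. 16 of 54 ribosomal protein genes were by a peak (29.6%, interval 17.98 to 43.6), against 2.65% of other genes (odds ratio 15.5, exact adjusted p = 1.38e-11). Besides rpl-3, rpl-15 and rpl-35, the highest was rps-1 of the small subunit (WBGene00004470, peak III 4475490 to 4475819, signal 101, 263 bp from the start), ranked 42 in replicate 1 and 31 in replicate 2. 5 of 14 heat shock genes were by a peak (35.7%, interval 12.8 to 64.9; odds ratio 19.8, adjusted p = 0.000259 by Fisher's exact test). These included dnj-13, a DnaJ co-chaperone gene (WBGene00001031, peak II 11545328 to 11545657 in an intron of dhgd-1, signal 55.1), hsp-3, an endoplasmic reticulum chaperone gene (WBGene00002007, X 6092020 to 6092349, 49.7), hsp-1, the constitutive cytosolic Hsp70 gene (WBGene00002005, IV 17278392 to 17278721, 46.3), and hsp-12.2, a small heat shock protein gene (WBGene00002011, III 8136651 to 8136980, 28.6). The hsp-12.2 peak ranked 289 in replicate 2 and 11120 in replicate 1. A peak by hsp-12.3 (IV 9444643 to 9444972, signal 27.2), a gene outside the naming rule, was named after its values were seen. It overlapped a stronger entry assigned to F38E11.9 (IV 9444440 to 9444769, signal 37.4). Both entries had ranks 123 in replicate 1 and 668 in replicate 2, so they may reflect 1 region. The heat shock list did not pass with the highest nuclear regions of replicate 1 alone (odds ratio 10.2, exact adjusted p = 0.0521) or with assignment within 500 bp (odds ratio 10.8, adjusted p = 0.0556). This list was not tested against regions matched on GC content and gene start.

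The other 18 of the 20 lists did not pass, and no list passed as lower. The mitochondrial respiratory chain had 4 of 29 genes by a peak (odds ratio 5.67, adjusted p = 0.0532 by Fisher's exact test), molting and developmental timing 3 of 25 (odds ratio 4.82, adjusted p = 0.155), histones 2 of 17 (adjusted p = 0.317) and basic helix-loop-helix factors 2 of 19 (adjusted p = 0.321). 4 lists were higher at an unadjusted p under 0.05. With replicate 2 alone the odds ratio was 3.11 for molting and timing genes (2 genes), 2.23 for histones (1 gene) and 1.98 for basic helix-loop-helix factors (1 gene). With replicate 1 alone it was 3.25 (2 genes), 8.05 (3 genes) and 2.07 (1 gene), and none of these passed. The respiratory chain list passed among the upper 208 peaks (odds ratio 8.31, exact adjusted p = 0.0494), against all annotated genes (6.52, adjusted p = 0.0301) and without peaks near short RNA genes (6.53, adjusted p = 0.0330). The molting and timing genes were lin-41 (WBGene00003026, peak I 9343825 to 9344154, intergenic, signal 40.1), the steroid hormone receptor gene daf-12 (WBGene00000908, X 10637604 to 10637933, in its own intron, 31.0) and myrf-1 (WBGene00004134, II 10501513 to 10501842, in its own intron, 27.3). Nuclear receptor genes did not pass, with 4 of 189 (2.12%, interval 0.580 to 5.33, against 2.78%; odds ratio 0.755, adjusted p = 1 by Fisher's exact test). They were nhr-238 (WBGene00021611, V 1629383 to 1629712, intergenic, signal 58.1), nhr-119 (WBGene00003709, II 2800934 to 2801263, intergenic, 33.5), daf-12 and nhr-3 (WBGene00003602, X 14560267 to 14560596, in its own intron, 29.9). The peaks by nhr-119, nhr-3 and myrf-1 ranked 6820, 11095 and 4277 in replicate 1.

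Lists for metabolism, structure and signalling gave 1 of 100 cuticle collagens, 2 of 97 detoxification enzymes, 2 of 35 lipid metabolism genes, 2 of 91 neuropeptides, 1 of 49 homeobox factors and 1 of 16 vacuolar ATPase genes. Markers of single tissues did not differ from other genes by the test, with 1 of 89 markers over 7 lists by a peak (1.12%, interval 0.0284 to 6.10, against 2.79%; Fisher's exact test, p = 0.522). That gene was cgh-1, a germline RNA helicase gene (WBGene00000479, peak III 7498426 to 7498755, intergenic, signal 28.05), 1 of 6 germline markers. The cgh-1 peak ranked 1553 in replicate 1 and 372 in replicate 2. The counts were 0 of 15 for intestine, 0 of 17 for hypodermis and seam, 0 of 12 for body wall muscle, 0 of 13 for pharynx, 0 of 16 for neurons and 0 of 10 for excretory cells and glia. The upper limits of their intervals ran from 19.5% for hypodermis and seam to 30.8% for excretory cells and glia, so a modest excess was not detectable.

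**Figure D3:**
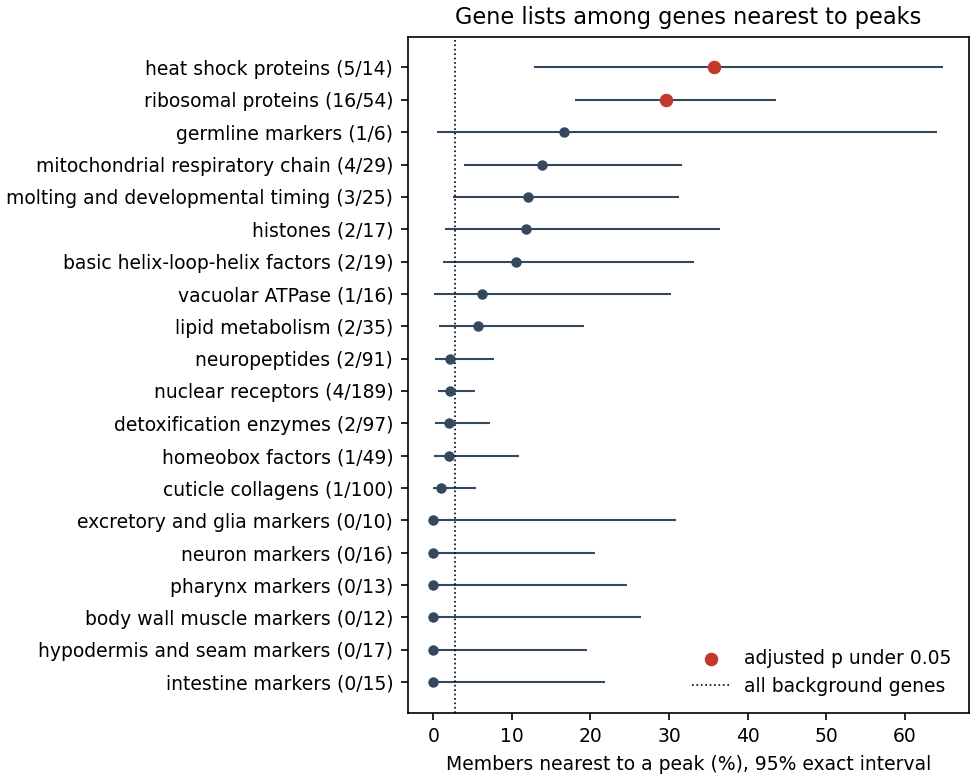
Share of the members of each of the 20 gene lists that are nearest to a peak (x axis, percent), with counts in brackets and 95% Clopper-Pearson intervals as bars. Ribosomal proteins (29.6%) and heat shock proteins (35.7%), in red, have adjusted p under 0.05, and the dotted line marks all background genes.

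Genes for short structural RNAs also lay close to peaks. A small nuclear RNA gene lay within 500 bp of the summit of 16 peaks (3.86%, interval 2.22 to 6.19, against 0.159% of background; odds ratio 25.2, exact adjusted p = 1.39e-15), and a small nucleolar RNA gene of 24 (5.78%, interval 3.74 to 8.48, against 0.582%; odds ratio 10.5, adjusted p = 1.39e-15). Transfer RNA genes were near 19 peaks (4.58% against 1.25%; odds ratio 3.79, adjusted p = 4.11e-06) and microRNA genes near 4 (0.964% against 0.291%; odds ratio 3.33, adjusted p = 0.0457 by Fisher's exact test). Ribosomal RNA genes were near none (0 of 415, upper limit of the interval 0.885%), against 2 of 29553 background regions (0.00677%). At so low a background share, a deficit in peaks could not have been seen. In total 61 peaks (14.7%, interval 11.4 to 18.5) lay near a gene of any of the 5 classes. Among the upper 208 peaks the transfer RNA class (odds ratio 1.88, exact adjusted p = 0.335) and the microRNA class (odds ratio 1.61, adjusted p = 0.583) did not pass, and microRNA did not with replicate 1 alone (odds ratio 2.47, adjusted p = 0.162). The small nucleolar RNA odds ratio was 3.90 with replicate 1 alone (10 peaks) and 5.45 among the upper 208 peaks (7 peaks). That of small nuclear RNA was 14.9 with replicate 1 alone, 15.7 with replicate 2 alone, 49.1 within 200 bp and 15.4 within 1000 bp. Both classes passed in each of these settings.

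In sequence, peaks were rich in GC, and the binding hexamers of nuclear receptors showed no excess that passed the test. Windows of 200 bp on the summits had a GC content of 43.8% ± 7.23 (SD, n = 415), against 34.6% ± 7.26 (SD, n = 29553) for background. They were therefore set against 2064 background windows matched on GC content (mean 43.6%). Annotation was not matched: coding exons held 18.6% of all background regions and 0.723% of peaks. The contrasts of patterns and hexamers may thus partly reflect coding sequence among the controls, whose share was not counted. The nuclear receptor core hexamer AGGTCA was in 4.10% of peaks and 6.44% of controls (odds ratio 0.620, exact adjusted p = 0.128), and AGTTCA in 6.51% and 9.88% (odds ratio 0.634, adjusted p = 0.0880). GAGAGAG was more frequent (17.6% against 10.1%, odds ratio 1.90, exact adjusted p = 0.000255), and the GATA factor site TGATAA less frequent (8.67% against 13.5%, odds ratio 0.610, adjusted p = 0.0334). In 100 bp windows neither passed (GAGAGAG odds ratio 1.69, exact adjusted p = 0.0634; TGATAA odds ratio 0.914, adjusted p = 0.914), and TGATAA also did not among the upper 208 peaks (odds ratio 0.733, adjusted p = 0.512) or with replicate 1 alone (0.857, adjusted p = 0.489). The AGTTCA deficit passed with replicate 2 alone (odds ratio 0.563, exact adjusted p = 0.0198), in 400 bp windows (0.611, adjusted p = 0.00209) and without GC matching (0.479, adjusted p = 0.000159).

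The other patterns did not pass: the E-box CACGTG (6.75% against 4.99%, exact adjusted p = 0.216), the AP-1 type site (1.69% against 1.74%, adjusted p = 1), the forkhead site GTAAACA (0.964% against 2.13%, adjusted p = 0.216), CAGCTG (6.51% against 6.69%, adjusted p = 1) and a run of T (15.2% against 11.5%, adjusted p = 0.0880). The run of T passed as higher without X peaks (odds ratio 1.65, exact adjusted p = 0.0141) and as lower without GC matching (0.483, adjusted p = 6.35e-08). Without GC matching the GAGAGAG odds ratio was 4.75, and CACGTG (odds ratio 2.20, exact adjusted p = 0.000627) and CAGCTG (1.75, adjusted p = 0.0141) passed as higher. In a search of all 2080 hexamers, counted with their reverse complements, 198 were more and 201 less frequent in peaks, 399 in all, and 222 passed with replicate 1 alone. CG was part of 115 of the 198 (58.1%, against 26.0% of all other hexamers) and of 27 of the 201 (13.4% against 30.7%), counts that were taken after the hexamers had been seen and that cover overlapping hexamers. Those with the lowest p by the exact test were ACGCGC (20% of peaks against 5.52% of controls, odds ratio 4.28, adjusted p = 1.60e-15), GACGCA (25.3% against 9.88%, odds ratio 3.09), CGCGCA (20.7% against 7.03%, odds ratio 3.46), AGTGCG (18.1% against 5.52%, odds ratio 3.77) and GCGCAC (19.8% against 6.64%, odds ratio 3.46).

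**Figure D4:**
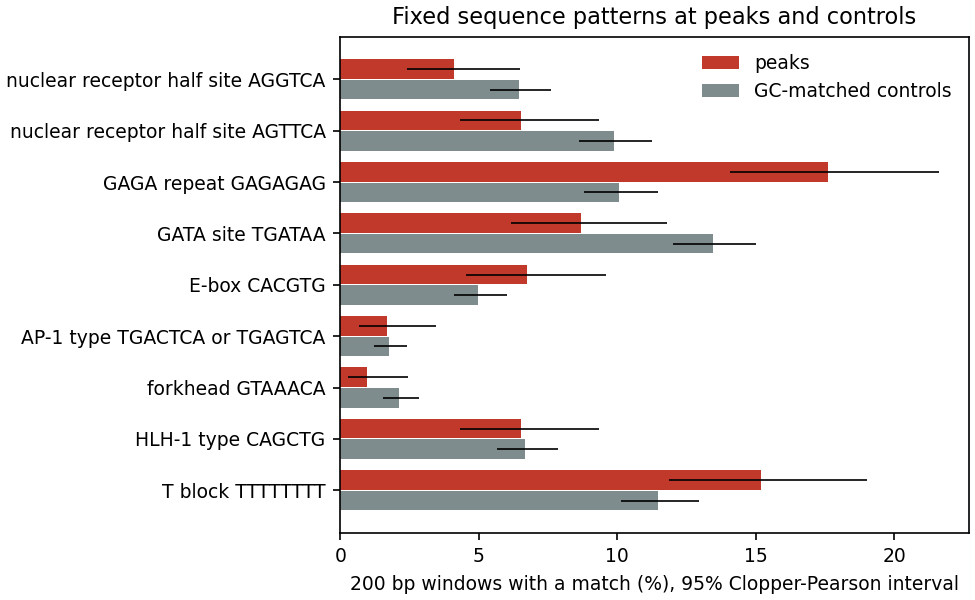
Share of 200 bp windows with at least 1 match to each fixed sequence pattern (x axis, percent), for the 415 peaks in red and 2064 GC-matched controls in grey, with 95% Clopper-Pearson intervals. GAGAGAG is more frequent in peaks (17.6% against 10.1%) and TGATAA less frequent (8.67% against 13.5%), and the nuclear receptor hexamers do not pass the test.

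The loci of the tagged gene and of unc-119 were examined because extra copies in a transgene can add reads to a locus. No peak lay within 15 kb of nhr-77 (WBGene00003667, I 12384277 to 12385731, minus strand) or of unc-119 (WBGene00006843, III 10902641 to 10908935, plus strand). The summed pooled signal per kb around nhr-77 was at percentile 48.7 among 19973 genes, and at a mean percentile of 37.8 ± 8.73 in the replicates (SD, n = 2). Around unc-119 it was at percentile 26.9 in the pooled list and 36.9 ± 33.9 in the replicates (SD, n = 2), with 12.97 in replicate 1 and 60.9 in replicate 2. Around nhr-77 the percentile was 9.50 with 30 kb on each side and 65.2 by count of regions, and around unc-119 it was 63.96 with 5 kb on each side. The lists were made with a control file, and the strain behind it is unknown here. A control with the same copies would offset them, so these values cannot show whether extra copies added reads.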

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

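The count of mitochondrial regions was examined only after the lists had been seen. The relaxed list of replicate 1 held 23 regions on the mitochondrial genome (0.0989% of its 23256 regions, interval 0.0627 to 0.148), a genome that the thresholded peaks do not touch. They ranked from 1 to 459, with 15 of them among the 25 highest regions of that replicate and 22 among its 415 highest. The relaxed list of replicate 2 held 0 of 30000, and a count of 0 allows up to 0.01% (3 counts of the total). Entries of a ranked list are not a random sample, so these limits do not measure mitochondrial signal. The pooled list held 0 although it was derived from both replicates, so a count of 0 in a list need not mean that mitochondrial reads were absent. The ce10 list of replicate 1 held 23 as well. Ranks in replicate 1 given for nuclear peaks count these regions, and so does the share of 41.2% of highest regions common to both replicates, which was 42.2% for nuclear regions only.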

How the results depend on the processing

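The settings limited to nuclear regions, to the 25 highest peaks, to peaks away from short RNA genes and to peaks off X were chosen only after the results had been seen. The share of highest regions common to both replicates (31.6 to 49.3%), their rank correlation (0.373 to 0.479) and the share of peaks near gene starts (40 to 66.7%, each above its own background) kept their direction and passed under every alternative run. Region midpoints nearly coincide with summits, as 386 of the 415 peaks had the same width of 330 bp, and gave the same 58.1% near gene starts, so they test little. The N highest pooled regions are the thresholded peaks themselves, so that setting tests nothing. Peaks found in both replicates numbered 177. X held 64% of the 25 highest peaks and 21.2 to 22.4% in lists without a replicate, newly passing in the former and with replicate 1 alone, and chromosome II fell to 8%, below its background. 1 gene list passed with assignment within 500 bp, and 1 to 2 without a replicate. Among the upper 208 peaks, 2 classes of short RNA, 1 pattern and 175 hexamers passed. Without a replicate, 1 to 3 patterns and 222 to 357 hexamers passed. In 100 bp windows 0 patterns (by Fisher's exact test) and 249 hexamers passed, and without GC matching 6 and 934. Without GC matching the odds ratio of CAGCTG turned to 1.75 and that of the run of T to 0.483, as AT-rich background replaced the matched windows. The ranks of the 25 highest peaks were 1 to 32 in replicate 2 and 12 to 56 in replicate 1, where mitochondrial regions are counted. Of these 50 ranks, 29 differed from the pooled rank by more than 1 SD of the replicates, and 21 did not. With 2 replicates this SD is set by the gap between the 2 ranks, so that count does not measure how stable the ranks are. The nhr-77 percentile was 31.6 to 44.0 without a replicate, 9.50 with 30 kb on each side and 65.2 by count of regions. That of unc-119 was 12.97 to 60.9 without a replicate and 63.96 with 5 kb on each side. Fewer peaks or shorter windows give fewer matches to test, but some odds ratios weakened as well. Examples given above are TGATAA in 100 bp windows and the transfer RNA class among the upper 208 peaks. The cause of these changes was not tested. Of 307 values of single lists, classes, patterns and chromosomes I to V under alternatives, that void setting left out and X counted apart, 255 kept their direction and side of the threshold, 10 no longer passed and 11 newly passed. A further 31 turned direction: 3 of these, chromosome II, CAGCTG and the run of T above, passed in at least 1 of the settings compared, and 28 passed in neither. Among those 28, odds ratios in the upper 208 peaks were 1.48 for homeobox factors, 1.498 for detoxification enzymes, 1.60 for neuropeptides, 1.27 for CAGCTG, and 0 for lipid metabolism, vacuolar ATPase and germline markers. Without a replicate they ran from 1.14 to 1.61 for detoxification enzymes, 0.358 to 1.98 for cuticle collagens, 0 to 2.38 for vacuolar ATPase, 0.799 to 1.27 for neuropeptides, 0 to 7.15 for germline markers, 0.448 to 1.45 for AP-1 and 0.815 to 1.22 for CAGCTG. Within 500 bp they were 1.19 for homeobox factors and 0 for molting genes and germline markers, and within 5000 bp 1.06 for nuclear receptors. With all genes within 1000 bp they were 0.910 for lipid metabolism, 1.14 for neuropeptides and 3.52 for excretory and glia markers. Against random draws the ratios to the mean drawn were 1.01 for homeobox factors and 1.04 for neuropeptides. In 100 bp windows they were 2.01 for AP-1, 1.30 for CAGCTG and 0.976 for the run of T, and AP-1 had 1.12 with controls also matched on gene start. Depth is unknown, so its limit cannot be given. No paired analysis was possible because there was only 1 group.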

Other observations

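The 8 tests of explanations below, and the count by clusters, were all chosen after the patterns had been seen, and the test of background on X also after its value had been seen. Many of the strongest X peaks hold a sequence known from another process. TCGCGCAGGGAG is a 12-base motif enriched on X that marks recruitment sites of the dosage compensation complex, which lowers X expression in hermaphrodites. Matches with up to 2 mismatches were found in 200 bp windows of 13 of the 16 X peaks among the 25 highest, 4 of the other 73 X peaks (5.48%), 7 of 326 autosomal peaks (2.15%) and 7 of 428 GC-matched X background windows (1.64%). All X peaks, at 17 of 89 (19.1%), exceeded autosomal peaks (odds ratio 10.8, p = 1.08e-07) and X background (odds ratio 14.2, p = 3.23e-09; Fisher's exact tests). Of the 16, 2 had an exact match and 8 had 1 mismatch. The exact matches lay at X 11094123 to 11094134 in the highest peak and at X 2997121 to 2997132 in the peak within Y41G9A.17, both on the minus strand. The match in the peak by xol-1 reads TCGCGCAGGGAA (X 8036433 to 8036444), and that in the window of the pks-1 peak reads TAGCGCAGGGAG (X 5429588 to 5429599, which runs past the end of the peak). With up to 3 mismatches the motif marked 14 of the 16 and 17.8% of autosomal peaks, so weak matches say little.

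Of the explanations for the strong X peaks, dosage compensation recruitment sites as their location may be the one to follow, since 81.25% of the X peaks among the 25 highest held the motif (interval 54.4 to 96.0). A library of another factor among the pair is argued against, as X gave at least 56% of the 25 highest nuclear regions in each replicate (28% in replicate 1 when mitochondrial regions are counted; the limit to nuclear regions was chosen after these had been seen), and more background on X by its 17.7% share of background regions. The motif alone, counted as any match with up to 1 mismatch, is argued against: 15 of 32 such genome matches on X and 0 of 37 on autosomes had a peak (Fisher's exact test, p = 9.98e-07). Several of the 15 share a peak: with matches within 200 bp joined, 11 of 27 clusters on X and 0 of 37 on autosomes had one (Fisher's exact test, p = 1.75e-05). X also held 3 exact matches, 2 of them with a peak, against 0 on autosomes, and joining lowered only the count on X. Exactness and clustering of matches were thus not held equal. Still, only 2 exact matches had a peak, while 11 clusters on X had one. Since the 32 matches on X formed 27 clusters, fewer than 11 clusters can hold several such copies. These counts argue against exactness, and against clustering of these matches, as the whole account of the difference between X and autosomes. A part played by either, or by weaker copies nearby, stays open. Recruitment of NHR-77 itself, regions open to many factors, and a property that both libraries share through antibody or control stay open and were not tested.

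The peaks by ribosomal protein genes could follow from GC content and closeness to gene starts, which peaks share. Against regions matched on both, the odds ratio of a peak lying by such a gene fell from 15.8 to 4.29 and still passed (Fisher's exact test, p = 5.66e-05), which argues against these features as the whole cause but not against a part. Short RNA genes beside them are argued against, because the list had an odds ratio of 16.3 (exact p = 1.46e-12) without peaks near short RNA genes. Broadly accessible promoters of highly expressed genes stay open as an untested source, since the design has no group that would test a biological cause.

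The peaks by snRNA and snoRNA genes could have the same origin in GC content and gene starts. With both matched, the odds ratio fell from 13.9 to 6.34 (exact p = 2.15e-13), which argues against them as the whole cause. Neighbouring ribosomal protein genes are argued against by an odds ratio of 14.3 without regions assigned to those genes (exact p = 1.63e-28), and only 1 of the 16 ribosomal protein peaks was also near such an RNA gene. Reads shared between copies of these RNA genes, and open chromatin at highly transcribed genes, stay open and were not tested.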
